A study of Musculus with 2 samples.

How the data were processed

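The material was the stromal vascular fraction (the cells left after mature fat cells are removed) of subcutaneous white adipose tissue (sWAT) from mice that the sample labels give as 5 weeks old. The text of the series instead describes mice of 2 months, so the age is unsettled. It was measured by 10x Genomics single-cell RNA sequencing in 1 control library (genotype WT) and 1 LPCAT3-AKO library (genotype LPCAT3 knockout). Per the labels, the tissue was minced, digested with type I collagenase with shaking, filtered and centrifuged to remove mature adipocytes, and red cells were lysed. The number of mice behind each library, the exons deleted and the 10x chemistry are not given in the sources used here. The study's bulk RNA sequencing of whole sWAT was not analysed here.

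The deposited matrices hold raw UMI counts per gene and barcode, in the unit "counts", as whole numbers without normalization. The submitters' processing notes name Cell Ranger 6.1.2, the mm10 genome build and Seurat 4.10. The raw counts show no step of Seurat, and the gene annotation release is not stated. Each matrix listed 32285 genes, and the lowest barcode totals were 500 and 505 UMIs. Genes are named by the deposited symbols. For 78 entries whose symbol several Ensembl identifiers share, the identifier with the most UMIs kept the symbol.

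The cell filter, the clustering settings, the size rule, the gene lists, the markers and the alternatives of a first list were fixed before the data were examined. A barcode was kept with 500 or more detected genes and at most 10% of its UMIs from genes named mt-. Scrublet, as implemented in scanpy, scored doublets in each library on its own. In each library the cells with the highest scores were removed, as many as 0.8% of the kept cells per 1000 kept cells. This removed 1235 control and 1088 LPCAT3-AKO cells, against 589 (4.74%) and 674 (5.78%) called by Scrublet's own threshold. A total of 21767 cells remained.

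Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch key, without genes named mt-, Rpl or Rps and without sex-linked genes. Cells of both libraries were clustered together without integration, on 30 principal components, 15 neighbours and Leiden resolution 1.0 with seed 0, giving 39 clusters after splitting. No deposited cell annotation was used here. The rule for naming clusters was set after the matrices had been seen, from 18 marker lists fixed before. A cluster showed a marker when at least 20% of its cells had a UMI of it and its level was at least 30% of the highest cluster. It took the class with the largest share of markers shown, at 3 or more. A cluster in which another class also showed 35% or more of its markers was clustered again. After this, some vascular endothelial-like clusters still showed 70% to 80% of mural markers and kept their class. They held 44, 38, 38 and 5 control and 72, 38, 43 and 8 LPCAT3-AKO cells. A cluster stayed unnamed when its 10 leading genes held more markers of another class than of its own, or, at low depth, none of its own. The unnamed cells (12 control and 30 LPCAT3-AKO) were left out of the class comparisons. States within the adipose stem and progenitor cell (ASPC), macrophage/monocyte and T cell classes were named on sub-clusters at resolution 0.5, when 60% or more of a state's markers were shown. Classes and states carry the ending "-like", because they rest on markers alone.

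UMIs were summed over the cells of a class in each library and divided by the summed total, giving UMIs of a gene relative to all UMIs of the class in that library, on the usual CPM scale. The log2 ratio was that of CPM + 1 in the LPCAT3-AKO library over the control library. Shares of cells carry exact (Clopper-Pearson) 95% intervals and CPM values exact Poisson 95% intervals. Ratios carry 95% intervals from the exact binomial interval of the pair of sums. All intervals cover counting error only. The floor for an undetected gene was 3 counts. With 1 library per group no test between genotypes was possible, no p-value was computed, and the spread between animals is unknown. Genes were instead listed by a size rule: 20 CPM or more in the library with the higher level, a ratio of 1.5 or more either way, and a counting interval that excludes 1. It was applied in the 7 classes with 100 or more cells in both libraries.

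The genes named were the 12 highest and 12 lowest log2 ratios past the size rule in ASPC-like cells, and the 5 highest and 5 lowest in each other class. Left out of this choice were genes named mt-, Rpl, Rps, Gm with digits, ending in Rik, haemoglobin and immunoglobulin genes, sex-linked genes, and markers of other classes. Also named were Lpcat3, the sex-linked genes, and up to 4 members of each list, by the highest CPM among those past the size rule, or among all members where none passed. Genes named outside this rule are said to be so. Some genes that the rule names are not reported here.

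The 28 fixed gene lists (1 of them of sex-linked genes) and the 10 state lists were summarised by the median log2 ratio of members at 5 CPM or more on average. Each median was set against 10000 random lists of the same size, matched on mean CPM in 10 bins. A percentile or range from random lists describes these 2 libraries and is no test between genotypes. Medians of lists in T cell- and NK cell-like cells, other than heat shock genes in a test that counts all classes, are not reported, because the classes hold few UMIs. Of 34 such medians outside the range of 95% of random lists, 24 took the opposite sign under at least 1 alternative. That choice was made after these values had been seen.

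The size rule was tested on simulated data drawn from these libraries' totals. At whole library depth, with 22546 genes run, all 100 genes set to 2-fold and all 100 set to 3-fold were recovered, and 0 of 5334 unaltered genes at 25 CPM or more were called. At 1% of that depth, above that of the T cell- and NK cell-like sums and below that of the epithelial-like sums, 15811 genes were run, 89.0% and 98.0% were recovered, and 120 of 5334 unaltered genes were called. Simulated counts carry no variation between cells or animals, so the test covers counting error alone.

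Alternatives covered the gene and mitochondrial limits of the cell filter, doublet removal, Leiden resolution, clustering each library on its own, leaving lymphocytes out of the shares, median-of-ratios scaling, the mean over cells, thinning each cell to 2000 UMIs, a pseudocount of 5 CPM, and the limits of the size rule and of list membership. The added alternatives, chosen after seeing the data, were clustering without interferon, inflammatory, immediate-early, heat shock and cell cycle genes, weighting sub-clusters alike in both libraries, and leaving out the sub-clusters led by interferon genes. The last removed 220 control and 11 LPCAT3-AKO ASPC-like cells and 238 and 12 macrophage/monocyte-like cells. Weighting alike used only sub-clusters with enough cells in both libraries, 9 in the ASPC-like and 9 in the macrophage/monocyte-like class. It therefore left out the interferon-led sub-clusters too.

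Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.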

Results

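The gene expression of single cells was measured in the stromal vascular fraction of sWAT, which holds fat cell precursors, immune cells and vessel cells, in 1 control library and 1 LPCAT3-AKO library. LPCAT3 is a lysophosphatidylcholine acyltransferase of the endoplasmic reticulum that places polyunsaturated fatty acids into phosphatidylcholine. The series asks how blocking this remodelling in adipose tissue bears on insulin sensitivity, and the comparison below asks which cells and genes of the fraction differed between the libraries. The control library held 13831 barcodes and 111669076 UMIs, with a median of 7758 UMIs and 2589 genes per barcode. The LPCAT3-AKO library held 12806 barcodes and 119355147 UMIs, with a median of 8361 UMIs and 2720 genes. After filtering and doublet removal, 11191 control and 10576 LPCAT3-AKO cells remained, with medians of 8077 and 8600 UMIs. With 1 library per group there are no replicates, so every difference below describes these 2 libraries, and intervals cover counting error only. Genes are called higher or lower past the size rule, which asks for 20 CPM, a ratio of 1.5 and a counting interval that excludes 1. Highest and lowest log2 ratios are given among the genes open to naming, which leaves out markers of other classes, haemoglobin genes and predicted genes.

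The targeted gene, Lpcat3, was present at similar levels in both libraries of this fraction, which lacks mature adipocytes. Over all kept cells its level was 26.7 CPM (25.7 to 27.8) in the control and 30.6 CPM (29.5 to 31.7) in the LPCAT3-AKO library. In ASPC-like cells it was 27.1 CPM in the control and 29.5 CPM in the LPCAT3-AKO library, in macrophage/monocyte-like cells 21.6 and 24.1, and in vascular endothelial-like cells 52.7 and 51.9. Epithelial-like cells had the highest level of the 7 compared classes, at 66.2 CPM in the control and 62.2 CPM in the LPCAT3-AKO library. Dendritic cell-like cells had 18.1 CPM (13.8 to 23.3) in the control and 12.1 CPM (8.51 to 16.7) in the LPCAT3-AKO library. No class passed the size rule for Lpcat3. A 10x tag can lie outside the deleted part of a transcript, so these values do not check the deletion. Both libraries had the pattern of female cells: Xist, the RNA that silences an X chromosome, was seen in 94.3% of control and 93.1% of LPCAT3-AKO cells. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 UMIs in either library, which allows up to 0.0324 and 0.0298 CPM, and Uty had 2 UMIs in the control and 0 in the LPCAT3-AKO library.

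The makeup of the fraction was dominated by ASPC-like and macrophage/monocyte-like cells in both libraries, with fewer macrophages and more precursors, epithelial and T cells in the knockout library. ASPC-like cells, the fibroblast-like fat cell precursors, made up 49.97% (49.0 to 50.9) of control and 54.1% (53.2 to 55.1) of LPCAT3-AKO cells. Macrophage/monocyte-like cells made up 39.5% (38.6 to 40.4) of control and 32.8% (31.9 to 33.7) of LPCAT3-AKO cells, a ratio of 0.830 (0.794 to 0.868). Epithelial-like cells, which carry keratins such as Krt8, made up 0.992% (0.817 to 1.19) and 2.55% (2.26 to 2.87), a ratio of 2.57 (2.06 to 3.24). T cell-like cells made up 1.09% of control and 1.57% of LPCAT3-AKO cells, a ratio of 1.44 (1.13 to 1.83). Vascular endothelial-like cells made up 2.03% and 2.55%, a ratio of 1.26 (1.05 to 1.51). Mural-like cells, the pericytes and smooth muscle of vessels, numbered 19 in the control and 33 in the LPCAT3-AKO library, a ratio of 1.84 (1.02 to 3.42), and B cell/plasma cell-like cells 10 and 22, a ratio of 2.33 (1.06 to 5.51). Most of the vascular endothelial-like cells of both libraries lay in clusters that also showed 70% to 80% of mural markers. Vascular endothelial-like and mural-like cells were thus not cleanly separated. For dendritic cell-like (4.09% and 3.68%), NK cell-like (1.11% and 1.01%), mast cell/basophil-like (0.617% and 0.605%) and Schwann-like cells (22 cells in each library) the interval of the ratio included 1. Lymphatic endothelial-like cells numbered 2 and 8, too few to compare. Mammary ducts lie in this depot. The log2 ratio of the epithelial-like share was 1.36, and 0.80 without doublet removal, where the class held 205 control and 334 LPCAT3-AKO cells in place of 111 and 270.

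**Figure D1:**
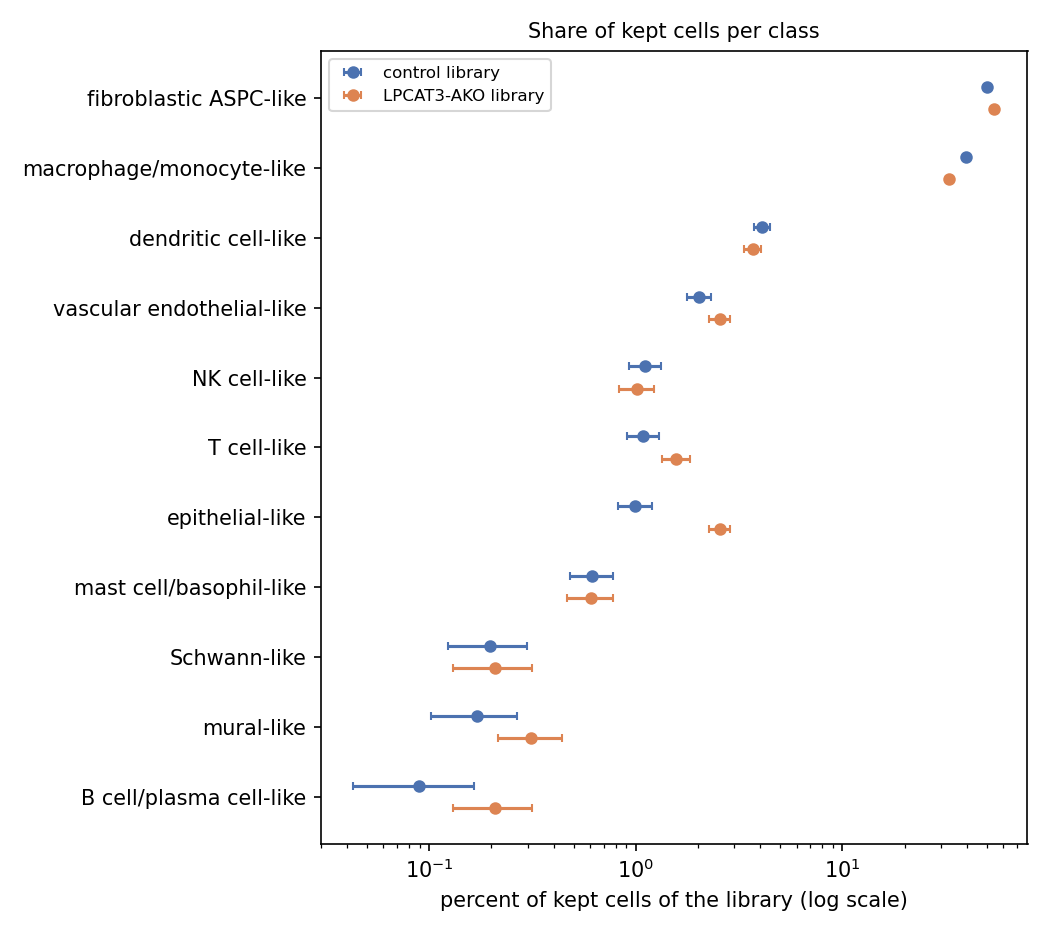
Percent of kept cells per class on a log axis, with 1 point per library and exact 95% binomial intervals as bars. Macrophage/monocyte-like cells sit at 39.5% in the control and 32.8% in the LPCAT3-AKO library, and epithelial-like cells at 0.992% and 2.55%.

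Within the ASPC-like class, the LPCAT3-AKO library held a larger share of cells with the profile of committed preadipocytes and a smaller share of interstitial progenitors. Icam1-high committed preadipocyte-like cells, named by markers such as Icam1, Pparg and Fabp4, made up 16.0% (15.1 to 17.0) of ASPC-like cells in the control and 26.3% (25.1 to 27.4) in the LPCAT3-AKO library, a ratio of 1.64 (1.51 to 1.79). Dpp4-high interstitial progenitor-like cells, the state placed upstream of committed preadipocytes, made up 62.9% (61.7 to 64.2) in the control and 54.5% (53.2 to 55.8) in the LPCAT3-AKO library, a ratio of 0.865 (0.824 to 0.908). This state included the sub-cluster led by interferon genes, at 3.93% of control and 0.192% of LPCAT3-AKO ASPC-like cells. Its other sub-clusters had 14.5% and 9.38%, 23.25% and 18.15%, 3.47% and 7.32%, 16.2% and 17.45%, and 1.56% and 1.96%. F3-high-like cells, a state linked to restraint of fat cell formation, made up 1.79% and 2.67%, a ratio of 1.495 (1.15 to 1.94). Their sub-cluster showed 87.5% of the F3-high markers and also 65.0% of the Icam1-high markers, so it met the limit of 60% for both states and took the larger. The remaining 19.3% of control and 16.6% of LPCAT3-AKO ASPC-like cells matched no state. Within the macrophage/monocyte-like class, resident-like cells (Mrc1, Cd163, Lyve1, Folr2) made up 69.3% (67.9 to 70.6) in the control and 58.4% (56.7 to 60.04) in the LPCAT3-AKO library. The resident-like state included the interferon-led sub-cluster of the class, at 5.38% of control and 0.346% of LPCAT3-AKO cells of the class. Its other sub-clusters had 22.8% and 16.7%, 14.8% and 15.9%, 24.8% and 23.9%, and 1.49% and 1.53%. Monocyte-like cells (Ly6c2, Ccr2, Plac8) made up 2.58% (2.13 to 3.09) and 7.26% (6.42 to 8.17), a ratio of 2.82 (2.25 to 3.55). The remaining 28.15% of control and 34.3% of LPCAT3-AKO macrophage/monocyte-like cells matched no state. Among them was a sub-cluster led by division genes such as Top2a and Mki67, at 3.44% and 8.93% of the class, a ratio of 2.60 (2.13 to 3.18). Naive-like cells numbered 42 of 122 T cell-like cells in the control (26.1% to 43.6%) and 83 of 166 in the LPCAT3-AKO library (42.2% to 57.9%), a ratio of 1.45 whose interval, 0.991 to 2.16, included 1. State shares rest on clusters formed from the same genes that name them. A single pair of libraries cannot separate genotype from animal or preparation.

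**Figure D2:**
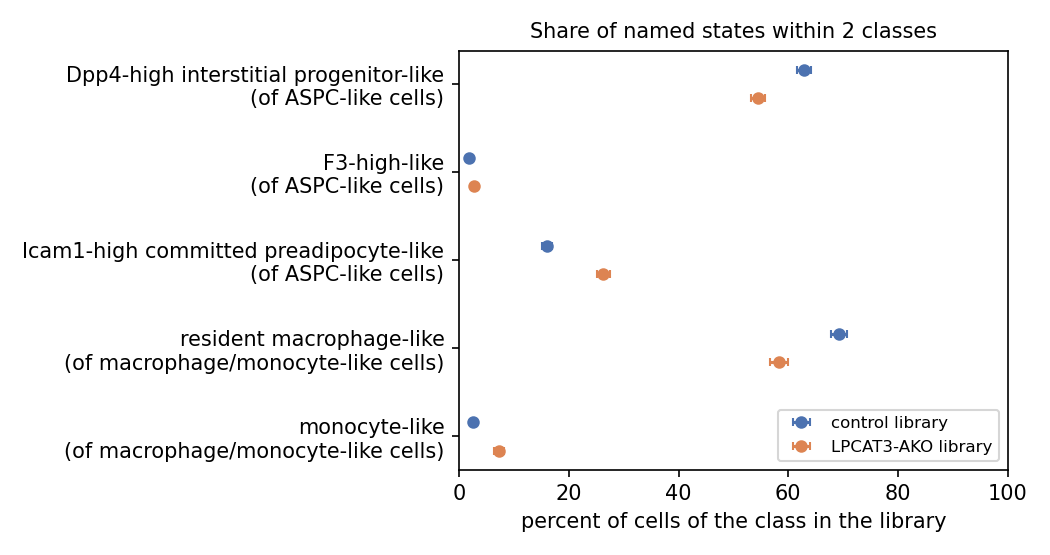
Percent of the cells of a class that fall in each named state, with 1 point per library and exact 95% binomial intervals as bars. Icam1-high committed preadipocyte-like cells sit at 16.0% of ASPC-like cells in the control and 26.3% in the LPCAT3-AKO library, and monocyte-like cells at 2.58% and 7.26% of macrophage/monocyte-like cells.

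In ASPC-like cells, the medians of inflammatory, interferon, immediate-early and heat shock genes were below those of random lists in the LPCAT3-AKO library, and the matrix median above, while a minority of the members of each list passed the size rule. The chemokine gene Ccl2 was lower, and the cytokine signalling inhibitors Socs1 and Socs3 were higher. Of 6063 genes at 20 CPM or more in either library, 75 were higher and 44 lower in the LPCAT3-AKO library past the size rule. Ccl2, the monocyte-attracting chemokine, had the lowest log2 ratio outside markers of other classes and predicted genes, with 576.9 CPM in the control and 217.9 CPM in the LPCAT3-AKO library (-1.40; interval of the ratio 0.370 to 0.386). Serpina3n, a secreted serine protease inhibitor, had 48.3 CPM in the control and 145 CPM in the LPCAT3-AKO library (log2 ratio 1.57; interval of the ratio 2.88 to 3.15). Socs3, an inhibitor of JAK-STAT signalling, had 180.3 CPM in the control and 410.7 CPM in the LPCAT3-AKO library (log2 ratio 1.18), and its relative Socs1 29.7 and 74.5 CPM (1.30).

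The inflammatory cytokine and NF-kB list had a median log2 ratio of -0.26 over 26 measured members, outside the range of 95% of random lists (-0.08 to 0.07), and of -0.13 without doublet removal. Of these, 7 were lower and 1, Cxcl14, was higher. Besides Ccl2, the lower members included the neutrophil-attracting chemokine Cxcl1 (1216 and 680.3 CPM, log2 ratio -0.84), the NF-kB inhibitor Nfkbia (1078 and 697 CPM, -0.63) and the alarmin Il33 (237 and 154 CPM, -0.62). Tnfaip3, a brake on NF-kB signalling, was also lower (113 and 61.4 CPM, log2 ratio -0.87). The interferon response list had a median of -0.22 over 35 members (random lists -0.06 to 0.06), with 5 lower and 0 higher. They were the antiviral genes Rsad2 (71.4 and 29.0 CPM, -1.27), Ifit1 (231 and 120 CPM, -0.95), Ifit3 (123 and 77.8 CPM, -0.65) and Isg15 (264 and 174 CPM, -0.60), and Igtp. The summed level of the list was 8186 CPM in the control and 8406 CPM in the LPCAT3-AKO library, with its abundant member Ifi27l2a at 1864 and 2531 CPM. The interferon median was smaller, -0.13, without the sub-clusters led by interferon genes, and -0.05 with sub-clusters weighted alike, which leaves those out too. Under that weighting Rsad2 had -0.56, Ifit1 -0.44, Isg15 -0.25 and Il33 -0.38, and Ifit3 stood at 0.00. Heat shock genes had a median of -0.27 over 14 members, with the small chaperone Hspb1 (110 and 53.7 CPM, -1.03, and -0.603 with sub-clusters weighted alike) and Hspa1a (80.1 and 52.1 CPM, -0.61) lower. The immediate-early list, genes that dissociation also induces, had a median of -0.19 over 27 members, with Fosb (1211 and 764.8 CPM, -0.66), Ier5 (284 and 189 CPM, -0.59) and Nr4a3 (55.8 and 29.4 CPM, -0.90) lower and Socs3 higher, and Ier5 had -0.38 with sub-clusters weighted alike. MHC class II genes had a median of -0.17 over 6 members, none past the size rule, with Cd74 at 101 and 87.5 CPM, and the median was 0.12 without doublet removal.

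The extracellular matrix list had a median of 0.23 over 46 measured members (random lists -0.06 to 0.05), with 6 higher and 0 lower. Markers of mural cells also had a median above random lists in this class, at 0.41 with summed levels of 134 and 189 CPM, as did those of Schwann cells, at 0.26 with 403.5 and 441 CPM. The higher matrix members were the basement membrane collagens Col4a1 (569 and 883.7 CPM, log2 ratio 0.64), Col4a2 and Col15a1 (142 and 291 CPM, 1.03), the fibrillar collagen Col5a3 (357 and 550.0 CPM, 0.62), the proteoglycan Bgn (253 and 449 CPM, 0.83) and the metalloprotease Mmp3 (292 and 452 CPM, 0.63). Adipocyte differentiation and lipid storage genes had a median of 0.17 over 22 members, of which lipoprotein lipase, Lpl (975.5 and 1680 CPM, 0.78), passed the size rule. Lpl was also the member that passed in the LXR target list (median 0.16 over 12 members) and in the endothelial fatty acid handling list (0.41 over 10). The medians of the marker lists had the same direction as the state shares, with 0.46 for the Icam1-high list, 0.68 for the F3-high list and -0.15 for the Dpp4-high list. The F3-high state held only 1.79% of control and 2.67% of LPCAT3-AKO ASPC-like cells. Whether its share accounts for the F3-high median was not tested. The macrophage lipid-associated list, which shares Lpl and Fabp4 with the Icam1-high list, had 0.41. With sub-clusters weighted alike in both libraries, an alternative chosen after seeing the data, 34 genes were higher and 23 lower. The medians were then 0.02 for adipocyte differentiation, 0.01 for LXR targets, 0.12 for endothelial fatty acid handling, 0.02 for the Icam1-high list, -0.010 for the Dpp4-high list and 0.13 for matrix. The lipid-associated list then had 0.12, and Lpl had 0.22, Col15a1 0.44, Col4a1 0.15, Col5a3 0.37, Mmp3 0.32 and Bgn 0.498. Other medians above the range of 95% of random lists were those of cholesterol synthesis (0.15, as Ebp with 46.6 and 50.4 CPM), anti-adipogenic and progenitor maintenance (0.16, as Gas1 with 193 and 281 CPM), fatty acid oxidation and peroxisome (0.10, as Cat with 70.2 and 79.8 CPM) and hypoxia, glycolysis and angiogenic factors (0.10). With sub-clusters weighted alike these 4 medians were 0.083, 0.090, 0.059 and 0.044, below the upper ends of the random lists (0.115, 0.104, 0.076 and 0.070). In the hypoxia list, the growth factor Fgf10 was higher (63.8 and 100.0 CPM, log2 ratio 0.64, and 0.08 with sub-clusters weighted alike). The G2M phase list had a median of 1.43 over 7 members, such as Mki67 (2.32 and 13.2 CPM) and Top2a (3.79 and 18.3 CPM), and none passed the size rule. That median was 0.23 as a mean over cells and 0.37 with cells thinned to 2000 UMIs.

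Lists of the pathway that LPCAT3 belongs to lay within the range of 95% of random lists in ASPC-like cells. Phospholipid acyl remodelling and phosphatidylcholine synthesis had a median of 0.03 over 24 members, of which only the choline kinase Chka passed the size rule (24.2 and 14.7 CPM, log2 ratio -0.68). Fatty acid desaturation and elongation had -0.07 over 16 members, with Scd1 at 78.4 and 91.4 CPM and Tecr at 83.4 and 100.3 CPM. Fatty acid synthesis had -0.06 over 10, with Me1 at 38.8 and 26.6 CPM. Insulin and IGF signalling had 0.05 over 20, of which the binding protein Igfbp7 was higher (307 and 480.8 CPM, 0.65, and 0.19 with sub-clusters weighted alike). Fibrogenic TGF-beta response had -0.04 over 17, of which Tgfbi was higher (40.0 and 60.4 CPM, 0.59). The mitochondrial oxidative phosphorylation list had -0.03 over 41 members, of which Atp5k, a small subunit of ATP synthase, was higher (142 and 229 CPM, 0.68). No member passed the size rule in the lists of caveolae (0.01), complement (0.02), oxidative stress and ferroptosis (0.01), prostaglandin synthesis (-0.02), unfolded protein response (-0.03), thermogenic genes (-0.06 over 3 members) or S phase (0.12).

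Among the 12 lowest genes in ASPC-like cells, those not yet given were Fyb2 (22.7 and 8.91 CPM, log2 ratio -1.26), Mrgprg (99.6 and 44.4 CPM, -1.15), Nexmif (23.8 and 10.99 CPM, -1.05), Rnase10 (70.3 and 34.1 CPM, -1.02) and Dmkn (66.6 and 36.3 CPM, -0.86). Among the 12 highest, Stmn1, a microtubule-destabilising protein of dividing cells, had 6.68 and 22.2 CPM (1.595). The matrix protein gene Cilp had 36.7 and 105 CPM (1.49), the aggrecanase Adamts4 33.6 and 85.3 CPM (1.32), Frem1 8.37 and 21.6 CPM (1.27), and the methyltransferase Inmt 20.7 and 50.4 CPM (1.24). AI506816 had 9.27 and 27.7 CPM (1.48) and Tril 22.4 and 45.6 CPM (0.997). Tpm2, a muscle tropomyosin, had 10.2 and 24.0 CPM (1.15), but 15.4% of its LPCAT3-AKO UMIs came from 1 cell. With sub-clusters weighted alike Stmn1 had 0.989, Frem1 0.647, Inmt 0.82 and Tpm2 0.62, and Frem1 had 0.69 with cells thinned to 2000 UMIs. Markers of other classes past the size rule included Fscn1 and S100b, which were higher, and Il1rl1, which was lower (51.8 and 8.02 CPM, log2 ratio -2.55). Among haemoglobin genes, a sign of red cell RNA that was looked at after the values had been seen, Hbb-bs had 18.6 CPM in the control and 40.3 CPM in the LPCAT3-AKO library and Hba-a1 6.05 and 23.9 CPM.

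**Figure D3:**
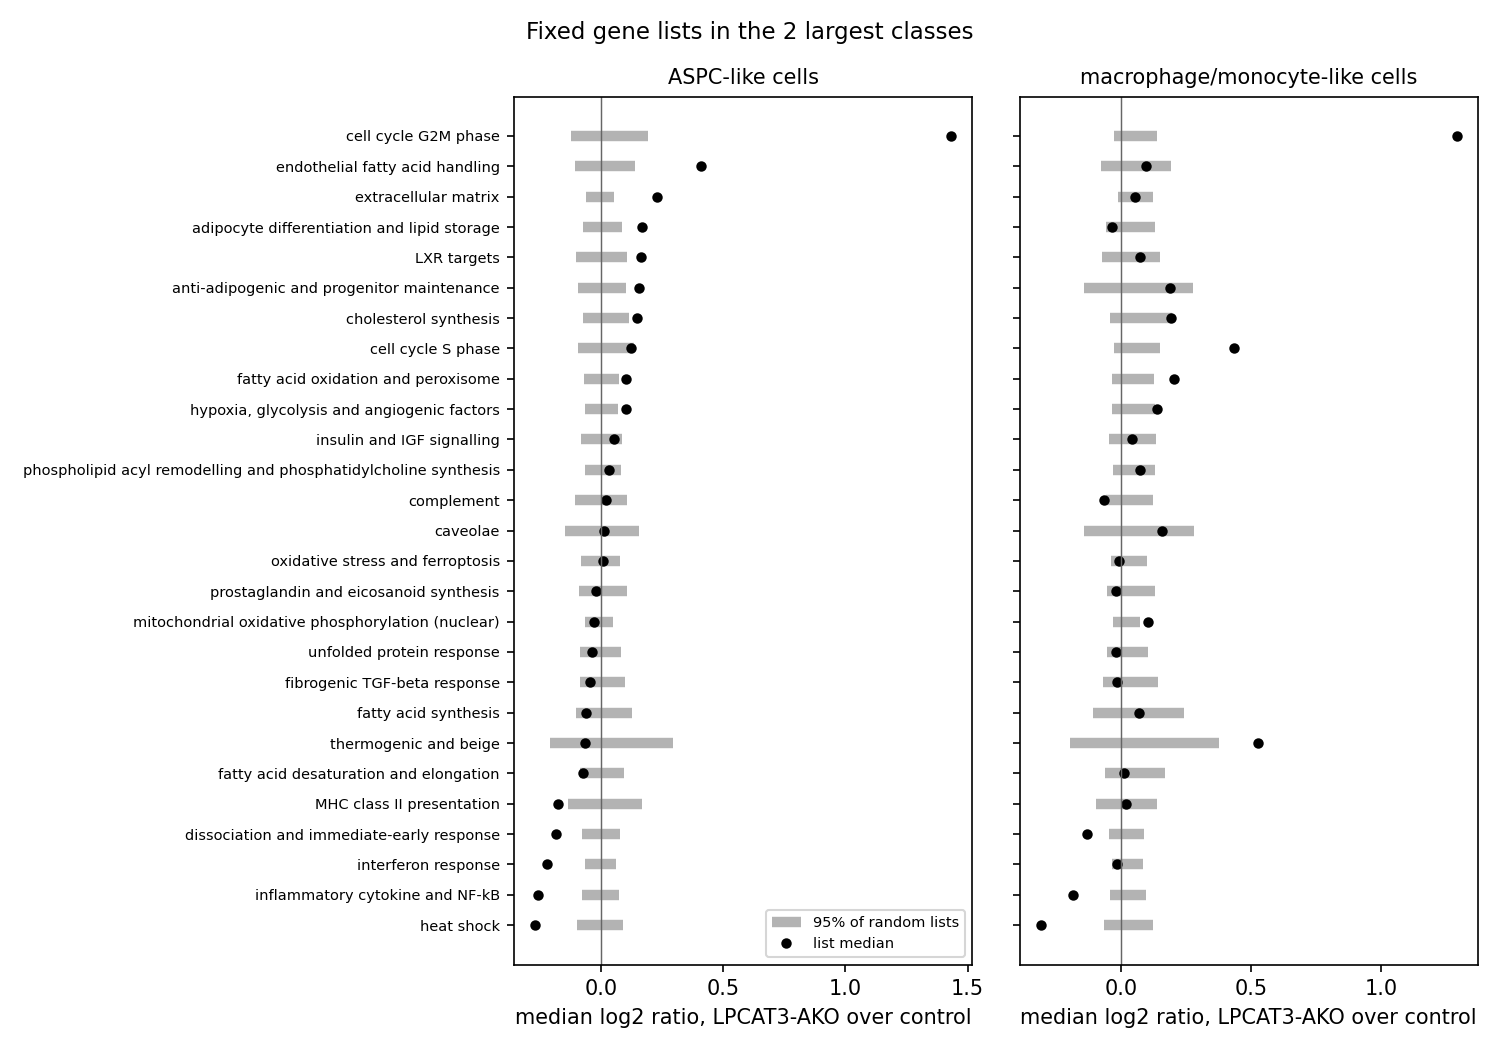
Median log2 ratio, LPCAT3-AKO over control, of each fixed gene list in ASPC-like (left) and macrophage/monocyte-like cells (right), as points, with grey bars for the range of 95% of matched random lists. In ASPC-like cells the heat shock (-0.27), inflammatory (-0.26) and interferon (-0.22) medians lie below their bars and the extracellular matrix median (0.23) above it.

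In macrophage/monocyte-like cells, Gdpd3 and a set of interferon-induced genes were lower in the LPCAT3-AKO library, and Ly6c2 and most G2M phase genes were higher. Of 5972 genes at 20 CPM or more in either library, 71 were higher and 30 lower past the size rule. Gdpd3, a lysophospholipase D that hydrolyses lysophospholipids, had the lowest log2 ratio, with 67.6 CPM in the control and 7.92 CPM in the LPCAT3-AKO library (-2.94; interval of the ratio 0.102 to 0.134). Ly6c2, a surface marker of classical monocytes and of the monocyte state, had the highest, with 15.2 and 163 CPM (3.34; interval of the ratio 9.77 to 11.8). Apoe, the apolipoprotein, was lower at 10070 CPM in the control and 6473 CPM in the LPCAT3-AKO library (-0.64).

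The G2M phase list had a median of 1.29 over 27 members (random lists -0.03 to 0.14), with 20 higher and 0 lower, such as the mitotic genes Top2a (65.9 and 156 CPM, log2 ratio 1.23), Mki67 (68.8 and 145 CPM, 1.06), Cenpa (31.5 and 66.5 CPM, 1.06) and Cks2 (63.0 and 98.5 CPM, 0.64). The S phase list had 0.43 over 23, with the ribonucleotide reductase genes Rrm1 (38.2 and 60.9 CPM, 0.66) and Rrm2 (15.5 and 28.6 CPM, 0.85) and the licensing factor Cdt1 among 4 higher members. With sub-clusters weighted alike the medians were 0.32 and -0.03, Top2a had 0.12, Cenpa 0.67, Mki67 0.0049, Cks2 0.078, Rrm1 0.0036, Cdt1 0.31 and Rrm2 -0.24, and 22 genes were higher and 11 lower. The monocyte list had 0.39 over 11 members and the resident list -0.14 over 16, and 0.19 and -0.052 with sub-clusters weighted alike. The interferon response list had a median of -0.02 over 35 members, within the range of random lists, but 7 members were lower, among them Rsad2 (695 and 290 CPM, -1.26), Ifit1 (272 and 112 CPM, -1.27), the GTPase Iigp1 (202 and 105 CPM, -0.94) and Ifit3 (157 and 84.8 CPM, -0.88). Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was also lower (128 and 48.2 CPM, -1.39). Without the sub-cluster led by interferon genes 11 genes of any kind were lower, and Rsad2 had -0.21, Ifit1 -0.65, Ifit3 -0.17, Iigp1 -0.48 and Cmpk2 -0.36. The inflammatory cytokine and NF-kB list had -0.19 over 27 members, with the chemokine Ccl7 (942 and 559 CPM, -0.75) and the adhesion molecule Vcam1 (127 and 74.4 CPM, -0.77) lower. Ccl7 had -0.47 without the interferon-led sub-cluster and -0.24 with sub-clusters weighted alike. Heat shock genes had -0.31 over 14 and immediate-early genes -0.13 over 26, with no member past the size rule, such as Hspa8 (2491 and 2103 CPM) and Dusp1 (3472 and 3199 CPM). As a mean over cells, the inflammatory median was -0.075 and the immediate-early median -0.05, and the latter was -0.029 with sub-clusters weighted alike. Complement genes had -0.07 over 16, and 0.08 with sub-clusters weighted alike.

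Metabolic lists showed small differences in macrophage/monocyte-like cells. Fatty acid oxidation and peroxisome genes had a median of 0.20 over 22 members, such as Cpt1a (136 and 147 CPM) and Cat (67.8 and 84.0 CPM), and none passed the size rule. Oxidative phosphorylation had 0.10 over 41 members, with Atp5k higher (175 and 282 CPM, log2 ratio 0.68). Hypoxia, glycolysis and angiogenic factors had 0.14 over 25, but 0.076 with cells thinned to 2000 UMIs and 0.054 with sub-clusters weighted alike, within the range of random lists (-0.04 to 0.13). The thermogenic list had 0.53 over 3 low members, among them Ppargc1b at 9.04 and 13.5 CPM, or 0.08 over members with a UMI in each library. The other response and metabolic lists lay within the range of 95% of random lists. Phospholipid acyl remodelling had 0.07 over 24, with Pnpla7, a lysophospholipase, higher (27.8 and 43.8 CPM, 0.64), and LXR targets 0.07, with Apoe the lower member. Oxidative stress and ferroptosis had -0.01, with the metallothionein Mt2 lower (237 and 139 CPM, -0.76), at -0.385 without the interferon-led sub-cluster and -0.29 with sub-clusters weighted alike. In the remaining lists no member passed: cholesterol synthesis had 0.19, anti-adipogenic factors 0.19, caveolae 0.16, endothelial fatty acid handling 0.10, fatty acid synthesis 0.07, extracellular matrix 0.05, insulin and IGF signalling 0.04, MHC class II 0.02 and desaturation and elongation 0.01. Fibrogenic response, unfolded protein response and prostaglandin synthesis each had -0.02, and adipocyte differentiation had -0.03. The lipid-associated macrophage list had 0.07. The other named genes were Mid1 (41.6 and 15.7 CPM, -1.35), the nuclease Dnase1l3 (4.99 and 25.95 CPM, 2.17) and the division genes Nusap1 (12.8 and 43.6 CPM, 1.70), Cenpf (13.8 and 46.6 CPM, 1.69) and Hmmr (6.03 and 20.5 CPM, 1.61), which had 0.502, 0.56 and 0.40 with sub-clusters weighted alike. Markers of other classes contributed 0 genes past the size rule in either direction.

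In dendritic cell-like cells, the chemokine genes Ccl17 and Ccl22 were lower in the LPCAT3-AKO library, and 7 of 22 G2M phase genes were higher. Ccl17, a chemokine for T cells, had 337 CPM in the control and 58.8 CPM in the LPCAT3-AKO library (log2 ratio -2.50), and Ccl22, which acts on the same receptor, 853.6 and 214 CPM (-1.99). They were among 6 lower of 21 measured dendritic cell markers, with Ccr7 (511.5 and 261 CPM), Fscn1 (113 and 55.5 CPM), Il4i1 (75.7 and 32.3 CPM) and Cacnb3 (29.6 and 15.4 CPM), while Ccr9 was higher and the median of the markers was 0.011. Ccl17, Ccl22, Ccr7, Fscn1, Il4i1 and Apol7c, whose values follow, were leading genes of a small cluster of 26 control and 13 LPCAT3-AKO cells. Ccl22 and Ccr7 also led a cluster of 281 and 255 cells. Whether the lower levels follow from the fewer cells of the small cluster was not tested. Gdpd3 had 37.4 and 2.94 CPM (-3.28), Apol7c 61.6 and 7.51 CPM (-2.88) and the class II gene H2-Eb2 24.1 and 7.51 CPM (-1.56). Apol7c had -5.97 when each library was clustered on its own, and H2-Eb2 -2.71 with cells thinned to 2000 UMIs. The highest were the cytokine Il10 (6.94 and 26.5 CPM, 1.79), of whose LPCAT3-AKO UMIs 43.2% came from 1 cell and which had 0.999 with cells thinned, the mitotic genes Nusap1 (10.6 and 31.4 CPM, 1.49) and Cenpe (12.4 and 27.1 CPM, 1.07), the prostaglandin-degrading enzyme Hpgd (9.35 and 23.2 CPM, 1.22) and Klrb1b (17.2 and 39.2 CPM, 1.14). In all, 84 genes were higher and 74 lower of 5132. With cells thinned to 2000 UMIs 206 were higher and 123 lower. The number higher was 193 without doublet removal and 47 with a pseudocount of 5 CPM. The interferon list had a median of -0.11 over 32 members, with Rsad2 lower and Ifi27l2a and Gbp7 higher. The G2M list had 0.50 over 22, and 0.32 with cells thinned to 2000 UMIs, the matrix list 0.22 over 38 and the anti-adipogenic list 0.29 over 4, while the immediate-early list had 0.13 over 27, and -0.04 with at most 5% mitochondrial UMIs. Markers of ASPC in this class had a median of 0.20, with Dcn, a proteoglycan of fibroblasts, at 81.8 and 130 CPM. Without doublet removal the matrix median was 1.01 and the anti-adipogenic median 1.14, while the latter was 0.115 over members with a UMI in each library. The interferon median was -0.048 with 1000 or more genes per cell.

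In vascular endothelial-like cells, Gdpd3 was nearly absent from the LPCAT3-AKO library, with 395 UMIs (151 CPM, 136 to 166) in the control and 7 UMIs (2.36 CPM, 0.949 to 4.86) in the LPCAT3-AKO library, a log2 ratio of -5.50. It was detected in 55.1% of control and 2.59% of LPCAT3-AKO endothelial-like cells, at median depths of 9759 and 8842 UMIs. Of 6621 genes, 118 were higher and 53 lower past the size rule. The counts were 190 and 123 with cells thinned to 2000 UMIs and 208 and 97 with at most 5% mitochondrial UMIs. They were 71 and 26 with a pseudocount of 5 CPM. The other lowest genes were the histone gene Hist1h1b (50.01 and 21.2 CPM, -1.20), the pentraxin Ptx3 (43.5 and 18.9 CPM, -1.16), Eva1a (34.0 and 16.2 CPM, -1.03) and the peptide hormone gene Cck (47.3 and 23.3 CPM, -0.99). Without doublet removal Ptx3 had -0.15, and Hist1h1b, of whose control UMIs 24.4% came from 1 cell, had -0.47 when cells were clustered without response genes. The highest outside haemoglobin genes, predicted genes and markers of other classes were AI506816 (5.73 and 27.6 CPM, 2.09), the protease inhibitor Spint2 (8.40 and 21.6 CPM, 1.26), the chemokine Ccl11 (17.6 and 39.4 CPM, 1.12), Epb41l4a (9.16 and 20.9 CPM, 1.11) and the sulfatase Sulf1 (10.7 and 23.9 CPM, 1.09). Ccl11 had 0.57, Sulf1 2.09 and Eva1a -1.71 with cells thinned to 2000 UMIs, Ccl11 0.703 without doublet removal, and AI506816 1.17 as a mean over cells. Lists outside the range of 95% of random lists were anti-adipogenic factors (0.37 over 11, with Dlk1 higher), extracellular matrix (0.24 over 46, with Fbln2, Fbn1, Col14a1, Loxl1 and Lum higher), immediate-early genes (0.10 over 26, with Egr3 higher), heat shock (-0.12 over 14) and oxidative phosphorylation (-0.07 over 41). The matrix median was 0.57 when cells were clustered without response genes, and the anti-adipogenic median 0.14 over members at 20 CPM or more and 0.21 with at most 5% mitochondrial UMIs. Without doublet removal the immediate-early median was 0.034, and the oxidative phosphorylation median was -0.045 with at most 5% mitochondrial UMIs and -0.14 with Scrublet's own threshold. Most cells of the class lay in clusters that also showed 70% to 80% of mural markers, and their values were not separated from the rest. Markers of ASPC in the class moved with the matrix genes, at a median of 0.28. Haemoglobin genes were higher too, with Hbb-bs at 95.8 CPM in the control and 850.4 CPM in the LPCAT3-AKO library, against 29.6 and 19.0 CPM in macrophage/monocyte-like cells.

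In epithelial-like cells, most G2M phase, S phase and immediate-early genes and 11 of 24 inflammatory genes were higher in the LPCAT3-AKO library, by amounts that depended on which cells the filters kept. Of 6298 genes, 533 were higher and 467 lower, from 111 control and 270 LPCAT3-AKO cells with median depths of 16060 and 20990 UMIs. The G2M list had a median of 2.70 over 27 members with 21 higher, such as the centromere protein Cenpa (2.88 and 71.8 CPM, log2 ratio 4.23), the mitotic regulators Cdc20 (1.64 and 47.6 CPM, 4.20) and Ube2c (8.23 and 142 CPM, 3.95) and the cyclin Ccnb2 (1.64 and 44.6 CPM, 4.11). S phase genes had 1.099 over 23 with 16 higher. Immediate-early genes had 1.06 over 26 with 17 higher, inflammatory genes 0.54 over 24 with 11 higher and interferon genes 0.31 over 28 with 4 higher and 1 lower. With at most 5% mitochondrial UMIs the medians were 0.29 for G2M, 0.29 for S phase and 0.057 for immediate-early genes, and without doublet removal 0.57, 0.37 and 0.012. The counts of genes were then 266 higher and 208 lower, and 248 and 177, and with at most 5% Cenpa had 0.63, Cdc20 0.49, Ccnb2 0.37 and Ube2c 0.35. The interferon median was 0.029 over members at 20 CPM or more, and the inflammatory median 0.32 without doublet removal. The lowest genes were the cadherin Cdh13 (79.0 and 15.02 CPM, -2.32), Rasef (226 and 51.7 CPM, -2.11), Timp4 (43.6 and 9.77 CPM, -2.05), the sodium pump regulator Fxyd2 (1127 and 279 CPM, -2.01) and the calcium-binding S100g (50.6 and 13.1 CPM, -1.88), of whose control UMIs 48.0% came from 1 cell and which took the opposite sign as a mean over cells (0.35). With at most 5% mitochondrial UMIs Cdh13 had -1.305, Rasef -1.24 and Fxyd2 -1.29, and Timp4 had -1.36 as a mean over cells. RNA of other classes moved the same way: markers of ASPC had a median of 0.95 and of macrophages 0.52, and Dcn had 245 and 473 CPM. Beside these stood the medians of extracellular matrix (0.99), fibrogenic response (0.74), anti-adipogenic factors (0.84), adipocyte differentiation (0.47), and the Dpp4-high (0.67), Icam1-high (0.63) and F3-high (0.87) lists. Complement (0.41), MHC class II (0.32) and resident macrophage genes (0.36) took the opposite sign with up to 20% mitochondrial UMIs, at -0.02, -0.17 and -0.43. Cholesterol synthesis had 0.36, with Fdps, Idi1 and Pmvk higher, oxidative stress 0.26, oxidative phosphorylation 0.11 and unfolded protein response -0.23, with Hyou1, Asns and Trib3 lower. These medians also depended on the cells kept, as with matrix at 0.42 when each library was clustered on its own, adipocyte differentiation at 0.033 without doublet removal and unfolded protein response at -0.028 with cells thinned to 2000 UMIs. The values nearest 0 under any alternative were 0.19 for fibrogenic response, 0.296 for anti-adipogenic factors, 0.027 for the Dpp4-high list, 0.33 for the Icam1-high list and 0.27 for the F3-high list. They were 0.17 for cholesterol synthesis, 0.14 for oxidative stress and 0.059 for oxidative phosphorylation.

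T cell- and NK cell-like cells gave long gene lists from few UMIs. In T cell-like cells 369 genes were higher and 368 lower of 6450, from sums of 481579 and 659141 UMIs, and in NK cell-like cells 450 and 378 of 6449, from 468595 and 636960 UMIs. With cells thinned to 2000 UMIs the counts were 156 and 192 in T cell-like and 194 and 184 in NK cell-like cells. With each library clustered on its own, T cell-like cells had 590 and 576. In T cell-like cells the fibroblast genes Gas1 (20 UMIs), Ccn5 (16), Has2 (15) and Bgn (21, against 1 in the control) and the NKG2D ligand H60b (16) led the higher genes, and the first 3 and H60b had 0 UMIs in the control. The lower genes were led by the macrophage receptor Marco (18 control UMIs, all from 1 cell), S100a3 (14 against 1), the chemokine receptor Cx3cr1 (21 against 2), Slc13a3 (19 against 2) and the checkpoint gene Hus1 (10 against 1). In NK cell-like cells 10 of 14 NK cell markers were lower, among them Gzma, Prf1, Nkg7 and Eomes, and 16 of 27 macrophage markers were higher. The lowest outside markers of other classes were the muscle genes Ttn, Pvalb, Pgam2, Mybpc2 and Actn3, of whose control UMIs 97.4% to 100% came from 1 cell. The highest were the receptor Tnfrsf4 and the kinase Adk (14 UMIs each against 0), Cavin3 (13 against 0), the granzyme Gzmc (32 against 1, of which 93.8% from 1 cell) and Lpar1 (28 against 1). Markers of other classes made up 24 of the higher and 24 of the lower genes in T cell-like cells, and 33 and 14 in NK cell-like cells, with Dcn at 598 and 1405 CPM in T cell-like cells. A sub-cluster of 4 control and 7 LPCAT3-AKO T cell-like cells had ASPC markers such as Mfap5, Sema3c, Cd34 and Clec3b among its leading genes. Its median depth was 12090 UMIs, against 3044 and 2932 in the class. How much of the fibroblast RNA of the class lay in these few cells was not tested. Slc13a3, S100a3 and Has2 in T cell-like and Tnfrsf4 and Cavin3 in NK cell-like cells took the opposite sign under at least 1 alternative.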

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

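Of the tests in this part, that of cell depth for the Icam1-high share was set before its result was seen, and the others were chosen only after.

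In ASPC-like cells the interferon, inflammatory, immediate-early and heat shock medians favoured the control library, and in macrophage/monocyte-like cells the last 3 did, along with 7 interferon genes past the size rule. A handling difference that moves immediate-early genes alike in all classes is argued against only weakly by endothelial-like cells, a class picked after its sign had been seen. That list had a median log2 ratio of 0.10 there, at percentile 99.2 of random lists in the main setting. The median was at least 0.034 under each alternative, the lowest being without doublet removal. Heat shock medians lay below 0 in 7 of 7 classes, as a handling difference would give, but those of T cell-like (-0.35) and NK cell-like cells (-0.11) rest on few UMIs, the latter and the dendritic cell-like and epithelial-like medians lay within random lists, and the dendritic cell-like median reached 0.030 under an alternative. For the 8 interferon genes past the size rule, 19.0% of their excess in the control library was left in macrophage/monocyte-like cells without the interferon-led sub-cluster, 5.38% of the control cells. In ASPC-like cells 51.8% was left without 3.93% of the control cells. Neither remainder decides about free RNA of the control suspension, since grouping cells on such genes and taking out the highest group lowers the remainder by itself. Free RNA stays open, since the whole excess had a macrophage/monocyte-like to ASPC-like ratio of 2.71, within the bound of 3 set for it. The ratio of 22.0 between macrophage/monocyte-like and dendritic cell-like cells decides nothing for genes chosen in the other classes. Class-dependent handling, exposure or litter of the mice and the genotype are untested.

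The share of Icam1-high committed preadipocyte-like cells among ASPC-like cells was larger in the LPCAT3-AKO library. Depth of the cells is argued against as its cause, since with ASPC-like cells thinned to 2000 UMIs, leaving out those below that, the ratio of the shares was 1.61 (1.48 to 1.75). Grouping of cells on stress, interferon or cell cycle genes is argued against as well, since the ratio was 1.65 when cells were clustered without these genes. A different yield of the digestion, a difference between the animals other than genotype, and an effect of the genotype on precursor commitment stay open, and none was tested.

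Gdpd3 was lower in the LPCAT3-AKO library in several classes. Free RNA of the control suspension is argued against as the source in vascular endothelial-like cells, where the control level was 27.5 times that in ASPC-like cells. The control level was also higher in macrophage/monocyte-like (67.6 CPM, 64.7 to 70.6) and dendritic cell-like cells (37.4 CPM, 31.1 to 44.6) than in ASPC-like cells (5.48 CPM, 4.86 to 6.15). Free RNA at a like level in all classes is thus argued against as the main source in these 2 classes too. These comparisons leave free RNA open in the other classes, such as ASPC-like, T cell-like (7 UMIs) and mural-like cells (4 UMIs) of the control library. A few control cells are argued against too, since no cell held more than 4.84% of the control UMIs of the gene in the endothelial-like, macrophage/monocyte-like or dendritic cell-like class. The counting interval of the ratio lay below 1 in 6 of 13 groups of cells, unnamed cells included, which a sequence or strain difference between the mice would give and a response to the deletion would give too. These cannot be told apart, because each genotype has 1 library and the reads were not analysed here.

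Several list medians had opposite signs in a pair of classes and lay outside the range of 95% of random lists in both, and the difference between the classes was not tested. The interferon response list had -0.22 in ASPC-like and 0.31 in epithelial-like cells. Immediate-early genes had -0.19 in ASPC-like and 1.06 in epithelial-like cells, where the median was 0.012 without doublet removal. The inflammatory cytokine and NF-kB list had -0.26 in ASPC-like and 0.54 in epithelial-like cells. MHC class II genes had -0.17 in ASPC-like and 0.32 in epithelial-like cells, and both took the opposite sign under an alternative. Complement genes had -0.066 in macrophage/monocyte-like and 0.41 in epithelial-like cells, and both took the opposite sign under an alternative. Oxidative phosphorylation genes had -0.071 in vascular endothelial-like and 0.11 in epithelial-like cells.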

How the results depend on the processing

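Sub-cluster weighting, leaving out interferon-led sub-clusters, and clustering without response genes were chosen only after the results had been seen, and the other alternatives before. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. All alternatives that gave a value kept the direction of each class or state share whose interval excluded a ratio of 1. The log2 share ratio ranged from 0.11 to 0.16 for ASPC-like, -0.29 to -0.25 for macrophage/monocyte-like, 0.50 to 0.74 for T cell-like and 0.19 to 0.57 for vascular endothelial-like cells. It ranged from 0.61 to 0.74 for Icam1-high, 0.44 to 0.61 for F3-high and -0.27 to -0.19 for resident macrophage-like cells. Of the log2 ratios of named genes past the size rule, 1644 values stayed within the counting interval, 336 left it with the same sign and 13 took the opposite sign. For medians outside the range of random lists, 864 moved by less than the spread of those lists, 144 by more with the same sign and 11 took the opposite sign. These counts of medians leave out T cell- and NK cell-like cells. There 72 of 543 values took the opposite sign, in 24 of 34 lists.

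Counts past the size rule moved with the limits by construction. In ASPC-like cells 196 genes were higher and 89 lower at 5 CPM, 45 and 29 at 50 CPM, and 13 and 10 at a ratio of 2. In macrophage/monocyte-like cells the counts were 235 and 54, 20 and 19, and 26 and 6, and over the other classes 4487, 1638 and 1355. The other classes had 1780 without doublet removal and 1894 with Scrublet's own threshold. With sub-clusters weighted alike, ASPC-like cells had 34 higher and 23 lower and macrophage/monocyte-like cells 22 and 11, and without interferon-led sub-clusters the latter had 11 lower.

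Epithelial-like and Dpp4-high shares had main log2 ratios of 1.36 and -0.21. With 1000 genes they were 0.89 and -0.30, with at most 5% mitochondrial UMIs 0.85 and -0.31, and without doublet removal 0.80 and -0.28. The epithelial-like value was 0.84 with Scrublet's own threshold. The Dpp4-high value was -0.298 with 200 genes, -0.39 at resolution 0.5 and -0.34 at resolution 2.0. The monocyte-like state went from 1.49 to 1.11 with 1000 genes.

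Outside the list medians of T cell- and NK cell-like cells, values of opposite sign were as follows. Sub-clusters weighted alike gave 0.0016 for Ifit3 in ASPC-like cells and 0.079 for complement, -0.033 for S phase and -0.24 for Rrm2 in macrophage/monocyte-like cells. S100g in epithelial-like cells had 0.35 as a mean over cells and 0.34 after thinning, which gave 2.96 for Slc13a3 in T cell-like cells. Slc13a3 had 0.21 and 0.55 with at most 5% and 20% mitochondrial UMIs and 1.06 without doublet removal. With at most 5%, immediate-early genes had -0.036 in dendritic cell-like cells. In epithelial-like cells, resident macrophage genes had -0.084 with 1000 genes, -0.43 with up to 20% mitochondrial UMIs, -0.23 without doublet removal and -0.023 with each library clustered on its own. With up to 20%, MHC class II genes had -0.17 and complement -0.021 there, and complement -0.050 with each library on its own. Doublets kept gave 0.12 for MHC class II in ASPC-like cells and -1.48 for Has2 in T cell-like cells. Cavin3 in NK cell-like cells had -0.42 with Scrublet's own threshold and -1.14 with each library on its own, where Tnfrsf4 had -1.81 and S100a3 in T cell-like cells 1.19. Apart from the count limits, the cause was not tested.

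No value was had for B cell/plasma cell-like cells with 1000 genes, at most 5% mitochondrial UMIs or each library on its own. None was had for mural-like cells without doublet removal, with Scrublet's own threshold, at resolution 0.5 or with each library on its own, nor for the monocyte-like state with Scrublet's own threshold or at resolution 0.5. Thinning left out cells under 2000 UMIs, 203 control and 163 LPCAT3-AKO cells of the ASPC-like and 366 and 229 of the macrophage/monocyte-like class.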

Other observations

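No test is reported in this part, and its genes were picked after their values had been seen. Some genes passed the size rule the same way in at least 4 of the 7 compared classes. A strain difference between the mice and the shortness of transcripts such as Rps28, Rps29, Rpl38 and Atp5k were not looked into as sources of these values, since reads and a genome were not used here. Atp5k, a small subunit of ATP synthase, was higher in the LPCAT3-AKO library in 7 classes, from 0.61 in dendritic cell-like to 0.999 in epithelial-like cells on the log2 scale. The ribosomal protein gene Rps29 was higher in 6 classes, with 3367 and 5203 CPM in ASPC-like cells. In 4 classes each, Rpl38 (1742 and 2646 CPM in ASPC-like cells) and Rps28 (2812 and 5263 CPM in T cell-like cells) were higher. Mid1, a ubiquitin ligase gene of the X chromosome, was lower in 6 classes, with 46.5 and 21.9 CPM in dendritic cell-like and 22.1 and 11.1 CPM in vascular endothelial-like cells. AI506816 was higher in 5 classes, with 9.53 and 20.5 CPM in macrophage/monocyte-like cells. Hes1, a target of Notch signalling, was higher in 4, with 84.6 and 127.9 CPM in ASPC-like and 415 and 624 CPM in vascular endothelial-like cells. Ifi27l2a was also higher in 4, with 783 and 1250 CPM in dendritic cell-like and 123 and 229 CPM in vascular endothelial-like cells. The survival gene Bcl2a1d was lower in 4, with 523.5 and 266 CPM in dendritic cell-like and 83.8 and 48.6 CPM in macrophage/monocyte-like cells, and Hspa1a was lower in 4. The fibroblast genes Dcn, Lum, Ogn and Emilin2 were higher in 4 or 5 classes and Lpl in 4, and Dcn did not pass the size rule in ASPC-like cells (8114 and 8736 CPM).

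Krt8, a keratin of epithelial cells, was detected below the 20 CPM of the size rule in classes that should lack it. Its level was 3.62 CPM in the control and 7.89 CPM in the LPCAT3-AKO library in ASPC-like cells, with a UMI in 3.15% and 6.80% of cells. In macrophage/monocyte-like cells it was 5.32 and 10.5 CPM, in 3.50% and 8.70% of cells, and in dendritic cell-like cells 5.13 and 11.8 CPM. Gdpd3 had 5.48 CPM in the control and 0.594 CPM in the LPCAT3-AKO library in ASPC-like cells, in 4.38% and 0.542% of cells. In mural-like cells it had 4 UMIs in the control and 0 in the LPCAT3-AKO library, and in T cell-like cells 7 and 0.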
